A study of Zea mays with 6 samples.

How the data were processed

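Leaf RNA of Zea mays was sequenced in 6 libraries, 3 of an LW group and 3 of a CW group. Per the labels' protocols, poly(A) RNA was isolated from total RNA; the same protocol also names a poly(A)- fraction and an adipose type, which do not match leaf mRNA, so the selection step is not settled. Libraries were sequenced as paired ends on an Illumina NovaSeq 6000 instrument. The submitters' processing notes name FastQC 0.10.1, HISAT2 2.0, StringTie 1.3.4 and edgeR without their roles. The genome build, the annotation release and whether counting used strand are not given in the sources used here; positions are those of the deposited table and their build is not stated. The groups were taken from the titles and the treatment labels. The source name of CW replicate 2 carries the number of replicate 3, and its title was followed. Nothing in the labels says that replicates came from separate plants or plots, so p-values measure the spread between these samples, which may be partly technical.

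The authors deposited 1 table of 45953 features with an FPKM value and a count per feature and library, with gene names, descriptions, coordinates and GO and KEGG terms. Every count column matched 1 sample's title, and no per-sample column was left over. The deposited counts are whole numbers, but 28.6% to 31.4% of the values from 1 to 40 are multiples of 4, a pattern of counts estimated from coverage, so they were treated as estimated counts rather than as reads. For that reason no counting interval is given, and the floor of 3 counts used where a group had none covers counting error only and may be too low. The deposited FPKM values are proportional to the counts: over 3125 genes with at least 2000 counts in each library, the ratio of count to FPKM deviated by 0.0977% or less in 99% of values after 1 factor per library and gene. Gene names come from the table, since the reference table at hand (NAM-5.0) holds other identifiers. No row lacked a gene.

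The design fixed before the data were examined named limma on log2(FPKM + 1) for a table of FPKM alone. It named edgeR for a table that also holds whole-number read counts. The deposited counts are whole but were treated as estimates, so they meet that condition only in part. The main test was edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with TMM factors and filterByExpr at its defaults (24704 genes kept). It used glmQLFit and glmQLFTest on all 6 libraries with the group as the only term. The choice matters: limma on log2(FPKM + 1) called 2487 of 19699 genes higher and 633 lower, against 701 and 592 with edgeR. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are counts per 1000000 (CPM) on TMM-scaled library sizes, as mean ± SD of 3 libraries, and folds are 2 to the power of the fitted log2 fold change. Where a group had no count, the fold is a bound against 3 counts in each library of that group. List medians had the same value with such genes placed at their bound.

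Lists of 33 gene groups were matched by words in gene names and descriptions. They were written before the data were examined, except that 4 patterns that had matched inside other words were corrected after the matched names were read; at that time the levels of the most abundant genes and of a few dehydrin, gigantea and Rubisco genes had been seen. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists, and again with an estimated correlation and with fry. Terms with 10 to 500 tested genes were tested by a two-sided Fisher's exact test against the tested genes that carry any term of the same source. Named genes followed a rule fixed before the data were examined. It took the 6 largest rises and 6 largest falls in log2(FPKM + 1) among called, described genes with a mean FPKM of at least 1 in the higher group and no overlap of groups. For the 10 lists with the largest share of called members it took the called member with the largest fold and that with the highest mean FPKM. This gave 30 genes, of which 1 overlaps another annotated gene. Principal components and correlations used log2(FPKM + 1) of the tested genes.

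No pair of libraries was alike within counting noise: chi-square per degree of freedom ran from 46.4 to 309 over pairs, on counts divided by 4. The smallest p that an exact test of 3 against 3 values can give is 0.1, so single quantities such as shares of counts are given without a test. On simulated counts for LW against CW with the 24704 genes' own means, library sizes and dispersions, edgeR recovered 26 of 50 genes changed 8-fold, 3 of 50 changed 4-fold and 0 of 50 changed 2-fold, with 1 call among unchanged genes. With those dispersions divided by 4 it recovered 47, 42 and 11. Camera, on the genes' own dispersions, and the enrichment test, on dispersions divided by 4, each found the 1 lowered list among 33 and no other. Genes were drawn independently of each other in this simulation. It therefore cannot show how camera at the preset correlation fares where genes of a list vary together. Alternatives planned for limma were run in edgeR where edgeR has the setting and in limma on FPKM otherwise. Alternatives changed the scaling, the filter, the pseudocount on FPKM, the tool (limma, and DESeq2 1.42.0), the trend, the block and the libraries used. Counts divided by 4, the filter on FPKM in 3 libraries, and further analyses without CW replicate 3 were added after seeing the data. So was limma on log2(FPKM + 1) as an alternative, although the design names it as the main test for FPKM alone.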

Results

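Leaf transcriptomes of maize (Zea mays) were compared between plants grown under 2 soil water regimes. The LW group of 3 libraries came from plants under drought that received water continuously by negative pressure irrigation, in which soil draws water from a reservoir held below atmospheric pressure. The CW group of 3 libraries came from plants in moist soil under drip irrigation. Irrigation method and soil water therefore differed together, and the comparison asks how leaf expression differed between the regimes as a whole. Estimated counts summed to 62327457, 75763960 and 84084375 in LW replicates 1 to 3 and to 42927751, 52515760 and 64067543 in CW replicates 1 to 3. Of 45953 annotated features, 24704 had enough counts to be tested.

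The groups separated along the largest principal component of log2(FPKM + 1), which held 56.1% of the variance. All LW libraries scored between 56.8 and 77.3 on it, and all CW libraries between -95.3 and -41.3. CW replicate 3 stood apart on the next component, at -81.8 against 35.0 and 26.1 in CW replicates 1 and 2. Across genes, Pearson correlations were 0.933 to 0.955 within LW, 0.910 to 0.947 within CW and 0.839 to 0.898 between the groups.

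**Figure D1:**
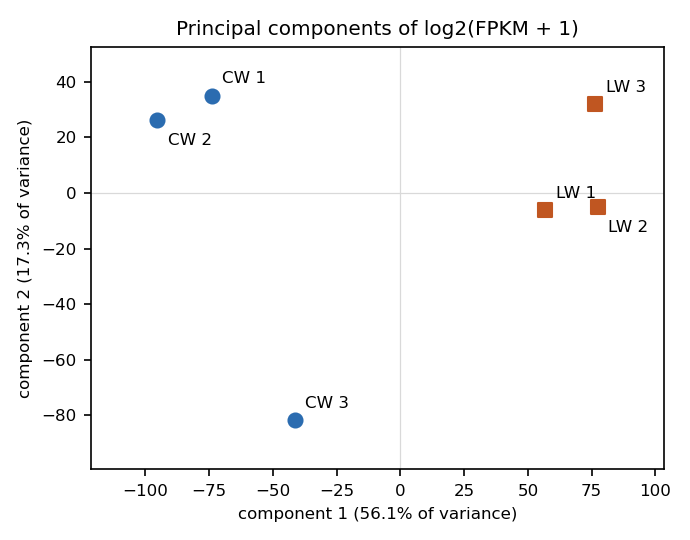
Scores of the 6 libraries on the principal components that hold 56.1% (horizontal axis) and 17.3% (vertical axis) of the variance of log2(FPKM + 1); circles are CW and squares LW libraries, numbered by replicate. The groups lie at opposite ends of the horizontal axis, and CW replicate 3 lies at -81.8 on the vertical axis, away from the other CW libraries.

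Genes of the light reactions of photosynthesis and of chlorophyll synthesis were mainly among those lower in LW, and genes of glutathione S-transferases, jasmonate synthesis and signalling, heat shock proteins, phenylpropanoid enzymes and cytosolic ribosomal proteins mainly among those higher. These lists passed camera's test at a preset correlation, and none did with an estimated one (smallest adjusted p = 0.178 with an estimated correlation). The loss is not an effect of correlation alone. Heat shock proteins, the only list named here with an estimate (0.003) below the preset 0.01, still went from an unadjusted camera p of 0.00101 to 0.0154. For photosystems the unadjusted camera p with an estimated correlation was 0.00750. With fry chlorophyll synthesis missed the threshold (adjusted p = 0.0612). Genes of photosystems and light harvesting took 2.70% ± 0.397 of all counts in LW and 11.99% ± 1.15 in CW (mean ± SD, n = 3 each). Glutathione S-transferase2 rose 103-fold, from 2.49 ± 2.44 to 257 ± 77.7 counts per 1000000 (CPM), and 12-oxo-phytodienoic acid reductase1, of a family of oxylipin reductases and not among the listed jasmonate genes, rose 65.0-fold, from 3.97 ± 2.70 to 259 ± 78.5 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 701 genes were higher and 592 lower in LW at an adjusted p under 0.05, and 694 and 590 of them differed at least 2-fold. In each of these 1293 genes all 3 LW values lay on one side of all 3 CW values. Over all tested genes 37.4% were separated in this way, where chance gives 10%.

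These counts fell when any 1 library other than CW replicate 3 was left out. In those fits 4265 to 5540 genes had an unadjusted p under 0.05, against 6103 with all libraries. Leaving out any 1 library removes the same number of residual degrees of freedom, so these alone do not explain why such fits differ from each other. Their part in the fall from all libraries was not separated from the role of each library. The numbers higher and lower were 172 and 70 without CW replicate 1, 1678 and 1287 without CW replicate 3, 5 and 1 without LW replicate 1, 4 and 0 without LW replicate 2, and 1 and 0 without LW replicate 3; without CW replicate 2 edgeR called no gene, with 5062 genes at an unadjusted p under 0.05. The gene lists lost called members in the same way. Of all 33 lists, none had a called member without CW replicate 2 or without any 1 LW library, except 1 glutathione S-transferase without LW replicate 1 and 1 without LW replicate 2. With libraries scaled by their totals alone 1425 genes were higher and 346 lower, a share of 80.5% higher against 54.2% with TMM factors, and the median of all genes moved from 0.065 to 0.422 on the log2 scale.

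Among the 33 lists, that of photosystems held the most falls. Of 92 tested genes of photosystems and light harvesting, 52 fell, 1 rose and 39 did not pass, with a median log2 fold change of -2.44. Adjusted over the list alone, 76 fell and 1 rose, and over all genes 65 fell without CW replicate 3 and 10 without CW replicate 1. The most abundant of the fallen genes, a chlorophyll a/b-binding protein 3-1 of photosystem I (Zm00001d046786, chromosome 9, 105955854 to 105957260), went from 13800 ± 2027 CPM in CW to 2496 ± 959 in LW, a 5.53-fold fall (log2 fold change -2.47, SE 0.45, adjusted p = 0.0345). Chlorophyll a-b binding protein 2 (Zm00001d044402) went from 62.5 ± 47.4 to 0.107 ± 0.0876 CPM, and chlorophyll a-b binding protein 48 (Zm00001d044396), near it on chromosome 3, from 51.1 ± 29.9 to 0.906 ± 1.07 CPM. The 1 gene of the list that rose, named after its values were seen, was a ferredoxin-NADP reductase (Zm00001d018794) at 27.7 ± 4.38 CPM in LW and 8.64 ± 3.19 in CW. The list lay lower than other genes with camera at a preset correlation (adjusted p = 7.90e-57), but not with an estimated one (adjusted p = 0.178 with an estimated correlation). Among annotation terms, photosynthesis held 69 of the genes that fell where 3.51 were expected, photosystem I 37 of its 49 tested genes, and the antenna proteins 21 of 24.

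Chlorophyll synthesis and carbon fixation each had 5 called members, all lower in LW with TMM scaling, but carbon fixation genes went both ways under other settings. Of 30 chlorophyll synthesis genes, glutamyl-tRNA reductase1 (Zm00001d026405), which catalyses the committed step of tetrapyrrole synthesis, fell 6.85-fold from 656 ± 193 to 95.7 ± 30.7 CPM. Magnesium-protoporphyrin IX monomethyl ester cyclase (Zm00001d008230) fell 5.02-fold from 2176 ± 574 to 434 ± 105 CPM. The other called members, named after their values were seen, were a pair of chlorophyllide a oxygenases and protochlorophyllide reductase C. Of 41 carbon fixation genes, the small subunits of Rubisco fell furthest. Small subunit1 (Zm00001d052595) fell 11.6-fold from 11080 ± 6811 to 952 ± 384 CPM, and small subunit2 (Zm00001d004894) 14.1-fold from 5635 ± 4124 to 400 ± 99.1 CPM; both stood at a lower level in CW replicate 3 (3503 and 901 CPM) than in the other CW libraries. Phosphoribulokinase, glyceraldehyde-3-phosphate dehydrogenase1 and pyruvate, orthophosphate dikinase2 also fell, named after their values were seen, whereas phosphoenolpyruvate carboxylase1 of the C4 pathway had an adjusted p of 0.882. Adjusted over the list alone, 10 chlorophyll synthesis genes fell and 2 rose, and 9 carbon fixation genes fell and 3 rose. Camera gave adjusted p = 1.08e-06 for chlorophyll synthesis and 0.00278 for carbon fixation, and for both adjusted p = 0.308 with an estimated correlation, while fry gave 0.0612 and 0.0664. Without CW replicate 3, 10 and 11 members fell and 1 of each list rose, and without CW replicate 1, 1 of each fell. Of the carbon fixation genes 5 fell and 2 rose scaled by totals, and 12 fell and 4 rose in DESeq2. In limma 7 fell and 6 rose on log2(FPKM + 1), 5 fell and 5 rose with a pseudocount of 0.1, 5 fell and 6 rose on values rescaled to sum to 1000000, and 2 fell and 1 rose after quantile normalization. DESeq2 called 10 chlorophyll synthesis genes lower and 2 higher, and limma 6 lower and 1 higher. Scaled by totals, the carbon fixation median turned from -0.30 to 0.05, which still lay below the median of all genes. Camera no longer passed for carbon fixation after quantile normalization (adjusted p = 0.266).

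Of 45 tested genes in the list of organelle-encoded genes, 4 fell, atpH, ndhC, petL and petG, and 41 did not pass, while adjusted over the list alone 22 fell. All 45 had a negative log2 fold change, with a median of -3.08. The list was matched by words and does not hold every such gene. RPS4 of the plastid genome stood in the ribosomal list and also fell, from 13.1 ± 2.21 to 2.90 ± 1.11 CPM (adjusted p = 0.0349, edgeR). Except for petG the called genes were named after their values were seen. The gene petG, for a small subunit of the cytochrome b6f complex, fell 18.0-fold from 56.8 ± 31.2 to 3.16 ± 2.13 CPM. Camera gave adjusted p = 5.71e-14, adjusted p = 0.308 with an estimated correlation, and fry adjusted p = 0.0886. Plastid-encoded genes took 0.246% ± 0.161 of counts in CW and 0.0290% ± 0.0187 in LW (n = 3 each); summed over the list, CW replicate 3 had 492 CPM against a mean of 3058 in CW replicates 1 and 2 and 185 in LW, and without it 20 members fell, against 0 without CW replicate 1 and 7 in limma after quantile normalization. The labels name poly(A) selection but also a poly(A)- fraction, so how organelle transcripts entered the libraries is not settled, and these shares depend on it.

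Glutathione S-transferases, which conjugate glutathione to reactive and foreign compounds, included 3 of the 6 largest rises on the scale of log2(FPKM + 1). Of 51 tested members, 12 rose, 1 fell and 38 did not pass; adjusted over the list alone 16 rose and 2 fell, and without CW replicate 3, 16 and 3, while 4 rose without CW replicate 1. Besides glutathione S-transferase2 (Zm00001d024839, chromosome 10, 90384434 to 90385822; adjusted p = 0.0275), glutathione transferase7 (Zm00001d042104) rose from 0.205 ± 0.271 to 95.7 ± 25.9 CPM and glutathione transferase31 (Zm00001d027557) 56.3-fold to 169 ± 52.3 CPM. The member called with the highest mean FPKM, glutathione S-transferase L2 (Zm00001d047765), rose 4.20-fold from 98.0 ± 3.98 to 412 ± 33.6 CPM. Glutathione transferase34 (Zm00001d029696) had no count in CW and 4.32 ± 1.21 CPM in LW, at least 65.8-fold higher against a floor of 3 counts per library. The member that fell, named after its value was seen, was Zm00001d023968. The list lay higher than other genes with camera (adjusted p = 7.59e-07), but not with an estimated correlation (adjusted p = 0.239 with an estimated correlation). The GO term glutathione metabolic process held 12 risen genes where 1.495 were expected (adjusted p = 4.75e-06, Fisher's exact test). The KEGG pathway glutathione metabolism held 11 where 3.349 were expected (adjusted p = 0.0202, Fisher's exact test). Outside this list the 6 largest rises on that scale included cytochrome P450 CYP709C14 (Zm00001d006947), which went 44.1-fold from 7.71 ± 6.37 to 341 ± 13.1 CPM.

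Of 56 tested genes of jasmonate synthesis and signalling, 9 rose and none fell, and adjusted over the list alone 20 rose; 51 had a positive log2 fold change, with a median of 1.35. Allene oxide cyclase 3 (Zm00001d047340), which forms the jasmonate precursor 12-oxo-phytodienoic acid, rose 5.52-fold from 76.1 ± 39.9 to 420 ± 205 CPM. A jasmonate-regulated gene 21 (Zm00001d042980) had no count in CW and 4.30 ± 2.66 CPM in LW, at least 65.4-fold higher. Allene oxide synthase, lipoxygenase4, ZIM-transcription factor 15 and ZIM-transcription factor 35 were among the others called, named after their values were seen. Outside the list, 12-oxo-phytodienoic acid reductase2 (Zm00001d044906), which lies beside reductase1 (Zm00001d044908) on chromosome 9, rose 44.8-fold from 7.52 ± 6.64 to 338 ± 47.0 CPM. The list lay higher with camera (adjusted p = 2.41e-08; adjusted p = 0.308 with an estimated correlation), while 13 members rose without CW replicate 3, 4 without CW replicate 1, 13 scaled by totals and 17 in limma after quantile normalization.

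Of 91 heat shock proteins 10 rose, among them heat-shock protein 101, and 1 fell, an HSP40/DnaJ peptide-binding protein (both named after their values were seen), and of 24 heat shock transcription factors 6 rose. Heat shock factor 7 (Zm00001d052738) rose 3.04-fold from 14.2 ± 3.64 to 43.1 ± 9.72 CPM, and factor 17 (Zm00001d033987) had no count in CW and 3.14 ± 1.22 CPM in LW, at least 47.8-fold higher. Camera gave adjusted p = 0.00278 and 0.00438 for these lists, and adjusted p = 0.178 and 0.308 with an estimated correlation; adjusted over the list alone 17 and 8 rose (1 heat shock protein fell), and without CW replicate 3, 13 and 6 rose and 3 heat shock proteins fell, while 3 and 2 rose without CW replicate 1 and 19 and 4 in limma after quantile normalization. Of 60 genes of lignin and phenylpropanoid synthesis 7 rose and 1, a Laccase-7 gene named after its value was seen, fell; adjusted over the list alone 12 rose and 1 fell, and without CW replicate 3, 14 and 1, while 1 rose without CW replicate 1 and 11 scaled by totals or in limma after quantile normalization. A cinnamyl-alcohol dehydrogenase family gene (Zm00001d024314) rose 15.9-fold from 40.7 ± 17.7 to 648 ± 462 CPM and cinnamyl alcohol dehydrogenase 6 (Zm00001d020400) went from 0.0916 ± 0.159 to 15.9 ± 3.80 CPM (camera adjusted p = 8.23e-05; adjusted p = 0.239 with an estimated correlation).

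Of 292 genes in the cytosolic ribosomal list 58 rose, 1 fell and 233 did not pass, with a median log2 fold change of 0.85, and adjusted over the list alone 141 rose and 12 fell. The rises ran from 1.96-fold to 12.01-fold with a median of 2.48-fold, and 60S ribosomal protein L10-3 (Zm00001d033128) rose 2.55-fold from 192 ± 17.2 to 490 ± 73.2 CPM. 60S ribosomal protein L31 (Zm00001d051662, named after its value was seen) rose 8.46-fold to 20.96 ± 6.66 CPM. 40S ribosomal protein S16 (Zm00001d023293) rose 12.01-fold to 6.60 ± 2.10 CPM, a value that is uncertain because the gene overlaps Zm00001d023292 on the opposite strand. The member that fell was RPS4 of the plastid genome, which is not a cytosolic protein. Camera gave adjusted p = 1.31e-12, and adjusted p = 0.308 with an estimated correlation; without CW replicate 3, 73 rose and 7 fell, and without CW replicate 1, 1 rose. The number that rose was 126 scaled by totals, 106 in limma after quantile normalization, 127 in DESeq2 and 164 in limma on log2(FPKM + 1). The KEGG ribosome pathway held 56 risen genes where 15.1 were expected.

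**Figure D2:**
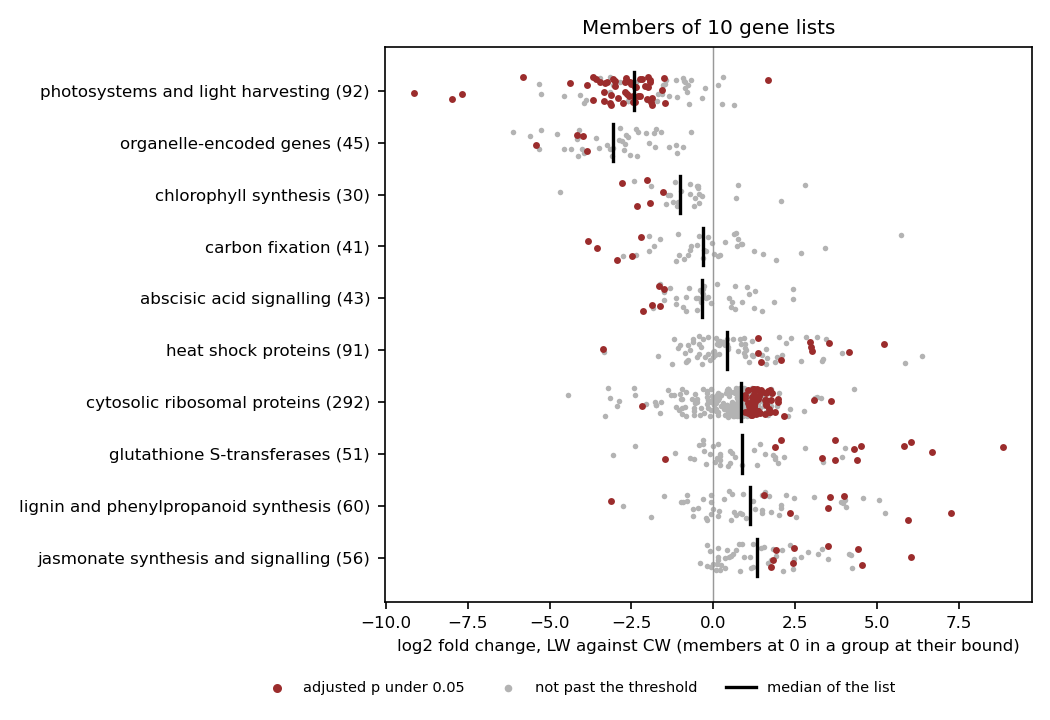
Log2 fold change of LW against CW for each tested member of 10 gene lists, with the number of members in brackets; members at 0 in a group are placed at their bound, red points pass an adjusted p of 0.05, grey points do not, and the black bar is the list's median. Medians run from -3.08 in organelle-encoded genes to 1.35 in jasmonate genes.

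Of 43 abscisic acid signalling genes 5 fell and none rose: Zm00001d018178, Zm00001d031790 and Zm00001d050018, which encode bZIP factors, Zm00001d020711, named like ABSCISIC ACID-INSENSITIVE 5, and protein phosphatase homolog13, named after their values were seen. Adjusted over the list alone 10 fell, and without CW replicate 3, 6 fell and 1 rose; 0 fell without CW replicate 1, and scaled by totals 3 fell and 1 rose. Camera placed the list lower (adjusted p = 0.00612; adjusted p = 0.308 with an estimated correlation; 0.0887 without CW replicate 3; fry 0.0712), and its median of -0.34 turned to 0.01 when libraries were scaled by totals. Of 15 genes of abscisic acid synthesis and breakdown a molybdenum cofactor sulfurase (Zm00001d006340) fell 3.24-fold from 205 ± 55.1 to 63.2 ± 19.8 CPM, and another rose 2.51-fold (Zm00001d046979, named after its value was seen). Neither was called without CW replicate 1, and scaled by totals 2 rose and 0 fell. Of 126 AP2/ERF factors 9 rose and 8 fell (camera adjusted p = 0.125), and without CW replicate 3, 19 rose and 11 fell (3 and 3 without CW replicate 1) and camera placed the list higher (adjusted p = 0.0138). It did so also after quantile normalization (0.0280), with 19 risen and 9 fallen in limma. AP2-EREBP factor 63 (Zm00001d042593) rose 22.2-fold to 9.99 ± 3.78 CPM and factor 172 (Zm00001d031796) 2.51-fold to 305 ± 52.8 CPM. Of 25 dehydrins and LEA proteins 1 rose, Dehydrin COR410, and 1 fell, a late embryogenesis abundant protein of group 2 (Zm00001d045220), both named after their values were seen (camera adjusted p = 0.166). In this list 2 rose and 1 fell without CW replicate 3, none was called without CW replicate 1, and 4 rose and 0 fell scaled by totals. None of 44 osmolyte synthesis genes and none of 26 clock genes passed edgeR's test over all genes. At an unadjusted p under 0.05, 6 osmolyte genes were higher and 6 lower, and 1 clock gene was higher and 3 lower. DESeq2 called 5 osmolyte genes higher and 5 lower, and 1 clock gene higher and 2 lower, and limma called 2 osmolyte genes higher, 1 lower and no clock gene. Of the osmolyte genes 1 rose scaled by totals and 2 fell after quantile normalization. Without CW replicate 3 edgeR called 1 gene higher and 1 lower in each of these lists. Camera placed neither list past the threshold (adjusted p = 0.366 and 0.338).

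Camera placed 20 of the 33 lists past the threshold, 13 higher and 7 lower in LW, and the genes named here for the remaining lists were chosen after their values were seen. Of 107 WRKY factors 9 rose and 3 fell (Zm00001d023336, Zm00001d037607 and Zm00001d047574), and without CW replicate 3, 18 rose and 4 fell, and without CW replicate 1, 2 rose. Of 71 NAC factors 5 rose (Zm00001d012527, Zm00001d019207, Zm00001d022424, Zm00001d024543 and Zm00001d040318) and 1 fell (Zm00001d039506), and without CW replicate 3, 12 rose and 1 fell, and without CW replicate 1, 2 rose. Of 81 genes of pathogen defence and benzoxazinoids 6 rose, 20 without CW replicate 3, 1 without CW replicate 1 and 12 scaled by totals. Of 39 ethylene genes 4 rose, Zm00001d002592, Zm00001d026060 and Zm00001d024853, which encode enzymes of ethylene synthesis, and an EIL factor (Zm00001d020939), and without CW replicate 3, 4 rose and 2 fell, and without CW replicate 1, 0 rose. Gibberellin 2-oxidase4 and a GID1L2 receptor rose among 33 gibberellin genes (9 rose and 1 fell without CW replicate 3), flavone synthase typeI1 and typeI2 among 42 flavonoid genes (8 rose without it) and ECERIFERUM 3 among 34 wax and cutin genes (7 rose without it); without CW replicate 1 these 3 lists had 1, 0 and 0 risen genes. Camera adjusted p of these 7 lists ran from 1.60e-05 for defence to 0.0114 for ethylene, and with an estimated correlation from 0.178 to 0.407. With fry WRKY, NAC and ethylene genes missed the threshold (adjusted p from 0.0612 to 0.0664). Scaled by totals, 5 flavonoid genes, 4 wax and cutin genes and 7 ethylene genes rose, 11 WRKY factors rose and 1 fell, 6 NAC factors rose and none fell, and the gibberellin count stayed at 2. The gibberellin call was lost in limma with a pseudocount of 0.1 (adjusted p = 0.0887) and on values rescaled to sum to 1000000 (0.0848).

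Of 31 genes of chlorophyll breakdown and senescence 3 fell, pheophorbide a oxygenase, senescence enhanced2b and DIN1 (median -0.20; camera adjusted p = 0.0183, and adjusted p = 0.239 with an estimated correlation); 6 fell and 2 rose without CW replicate 3 and 0 fell without CW replicate 1, and camera no longer passed without CW replicate 3 (adjusted p = 0.0683) or after quantile normalization (0.180). Of 89 genes of cell division and histones 4 histone genes fell (median -0.16; camera adjusted p = 0.0330, and adjusted p = 0.308 with an estimated correlation), Zm00001d005791, Zm00001d013300, Zm00001d029394 and Zm00001d038381; 10 fell and 1 rose without CW replicate 3 and 0 fell without CW replicate 1. Camera no longer passed without CW replicate 1 (adjusted p = 0.127), without LW replicate 1 (0.0799) or without a filter (0.0579). Fry gave adjusted p = 0.0848 for the histone list. Scaled by totals, these medians were 0.12 and 0.20, below the median of all genes, and 0 genes fell in either list while 1 senescence gene rose.

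Lists that camera did not place past the threshold held single genes, also named after their values were seen. Of 90 genes of sucrose and starch metabolism 3 rose, invertase1, sucrose transporter4 and a mitochondrial invertase (Zm00001d040735), and 5 fell, starch branching enzyme1 and enzyme3, sucrose transporter7 and a pair of beta-amylases (camera adjusted p = 0.0501). Camera placed that list lower without CW replicate 1, CW replicate 2 or LW replicate 1 (adjusted p from 0.0156 to 0.0400), scaled by totals (0.0452) and with a replicate block (0.0485). It did so too in limma with a pseudocount of 0.1 (0.00841), on values rescaled to sum to 1000000 (0.00669) and after quantile normalization (0.0280). In its other settings it did not pass (adjusted p from 0.05002 to 0.357). Its calls turned from mostly lower to 9 higher and 2 lower when scaled by totals. Of 52 antioxidant enzymes a glutathione peroxidase, a glutathione reductase and an ascorbate peroxidase homolog rose, and an ascorbate peroxidase (Zm00001d016802) and peroxiredoxin Q fell; the glutathione peroxidase (Zm00001d002704) rose 4.07-fold to 559.6 ± 65.2 CPM. Glutamine synthetase1 (Zm00001d026501) fell 7.95-fold from 567 ± 286 to 71.4 ± 39.4 CPM and Ammonium transporter 2 rose 4.97-fold, among 35 nitrogen genes. Aquaporin NIP1-2 rose among 21 aquaporins, cytokinin oxidase4b and Zm00001d015521 among 39 cytokinin genes, and ARF-transcription factor 3 and PIN-formed protein3 among 114 auxin genes, of which Zm00001d009532 fell. Of 84 cell wall genes 3 rose (Zm00001d024071, cellulose synthase3 and Zm00001d040649) and 2 fell (expansin-like6 and Zm00001d032495), and camera placed this list higher without CW replicate 1 (adjusted p = 0.0291), CW replicate 2 (0.0332) or LW replicate 1 (0.0170). Without CW replicate 3, 11 auxin genes rose and 4 fell, 8 sucrose and starch genes rose and 7 fell, and 3 antioxidant genes rose and 6 fell. Likewise 2 nitrogen genes rose and 3 fell, 1 aquaporin rose and 1 fell, 5 cytokinin genes rose and 1 fell, and 6 cell wall genes rose and 3 fell. Without CW replicate 1, 2 sucrose and starch genes fell, 2 antioxidant and 2 cytokinin genes rose, 3 cell wall genes rose and 1 fell, and no auxin, nitrogen or aquaporin gene was called. Scaled by totals, 7 cytokinin genes, 6 auxin genes and 3 nitrogen genes rose and none fell, 7 antioxidant and 6 cell wall genes rose and 2 of each fell, and 1 aquaporin rose. Median and mean differed in sign for antioxidant, clock, abscisic acid synthesis and aquaporin genes. Markers of seed, pollen and root, included as a sign of other tissue, had 1 of 41 called, root cap protein1, with camera adjusted p = 0.216 and fry adjusted p = 0.0134; 5 rose and 2 fell without CW replicate 3, none was called without CW replicate 1, and 3 rose scaled by totals.

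Further genes stood out by the size of their fall. The microRNA precursor zma-MIR408a (chromosome 3, 58127890 to 58128080) had no count in any LW library and 129 ± 105 CPM in CW, at least 3521-fold lower against a floor of 3 counts per library, with CW replicate 3 at 13.5 CPM. Little protein 1 (Zm00001d044078) fell 25.1-fold from 20.3 ± 13.4 to 0.813 ± 0.669 CPM and Cysteine protease 1 (Zm00001d013261) fell 31.1-fold from 83.1 ± 68.7 to 2.68 ± 1.65 CPM. Members of the gene families above have near-identical copies between which reads can be divided, so single members carry that uncertainty.

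**Figure D3:**
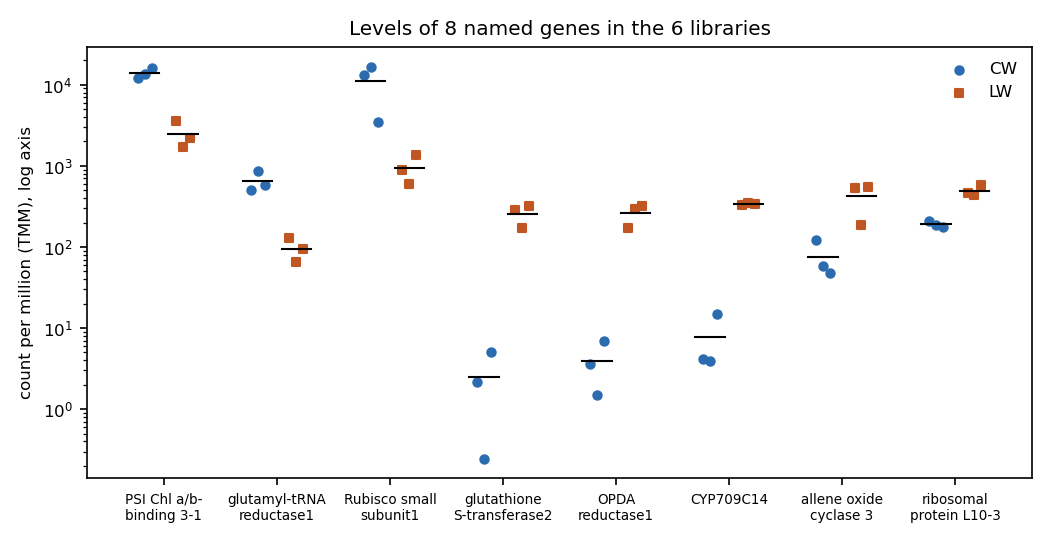
Counts per 1000000 (CPM) after TMM scaling, on a log axis, of 8 named genes in each CW (circles) and LW (squares) library, with bars at the group means (n = 3). No gene shows overlap between groups; CYP709C14 goes from a mean of 7.71 to 341 and Rubisco small subunit1 from 11080 to 952.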

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

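Counts divided by 4, the filter on FPKM in 3 libraries and terms without CW replicate 3 were chosen after seeing the data. So was limma on log2(FPKM + 1) as an alternative, although the design names it as the main test for FPKM alone. The direction of each of the 30 named genes was kept in all 679 combinations of gene and alternative; 496 stayed past the threshold and 183 did not, most of them with a library left out or with the block. All 1293 called genes kept their sign wherever they were tested, and 1293 were also called by DESeq2, 1270 with counts divided by 4, 1235 by limma with median ratios and 1209 without CW replicate 3. In all of these genes, the named ones included, LW and CW values did not overlap. Leaving out a library or changing the filter or pseudocount could therefore hardly reverse a sign, and the kept signs in those settings are no added evidence of direction. Over single libraries left out, the count of higher genes ran from 0 to 1678 and of lower genes from 0 to 1287. Each of these fits loses the same number of residual degrees of freedom, so that loss alone does not explain the range. Why the counts rose without CW replicate 3 was not tested. The numbers higher and lower were 2421 and 2036 with DESeq2, 2680 and 1987 at an unadjusted p with a fold of at least 2, 1425 and 346 with library totals, 1320 and 985 with limma on median ratios, 1158 and 978 after quantile normalization and 4183 and 1238 with array weights. Only the number higher moved by over 1.5 times in limma on log2(FPKM + 1), with 2487, with pseudocounts of 0.1 (2013) and 5 (2507) and on values rescaled to sum to 1000000 (3157). In these limma runs, which had no scaling between libraries beyond totals, 78.6% to 86.1% of called genes were higher. The share was 80.5% in edgeR with library totals, 57.3% in limma with median ratios and 54.2% after quantile normalization. The excess of higher genes thus went with the lack of such scaling. With a replicate block 2 and 1 genes were called. No label says that the numbers pair the samples. Deviations of same-numbered libraries correlated at -0.035, -0.002 and -0.251, below the 0.195 of CW replicate 1 with LW replicate 3. With 3 libraries per group these values cannot exclude pairing, so whether a block is due stays open. The block changed the list count only from 20 to 21. Lists past the threshold fell from 20 to 0 with an estimated correlation and to 13 with fry, and none of the 20 turned direction in 15 alternatives. Enriched terms were 57, 55 with the fold minimum and 84 without CW replicate 3. Terms were not counted with any other library left out, where fewer genes were called than with all libraries. At the spread of these libraries, simulated 2-fold changes were not recovered, so an uncalled gene may still differ by that much. In the simulation 26 of 50 genes changed 8-fold were called, but only 200 genes were changed there. With 1293 genes called in the real data the adjustment was less strict, and called ribosomal genes rose by as little as 1.96-fold. The simulated recovery is therefore no measure of the fold needed for a call here.

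The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05, and in each of the 4 results 1 split, the real one, gave as much. The real split called 701 higher and 592 lower genes and the highest other split 0. It put 20 lists past the threshold against 15, and enriched 57 terms against 0. Every other split has LW and CW libraries on both sides, so a group difference of any cause adds to its spread and lowers its calls. The contrast therefore does not say what set the groups apart.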

Other observations

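The tests of a swap, of mixed RNA, of scaling, of younger tissue and of time of day were chosen only after the results they measure were seen, and the gene lists of the opening paragraphs after the main results. MicroRNA precursors linked in plants to copper supply stood out among the falls. Of 28 tested microRNA precursor entries, which carry 23 names because some loci stand under more than 1 identifier, 3 fell in edgeR's test, zma-MIR408a, zma-MIR398b and zma-MIR528a, and 0 rose; at an unadjusted p under 0.05, 7 were lower and 0 higher, DESeq2 called 7 lower and 0 higher, and limma 8 lower and 1 higher. Without CW replicate 3, 4 entries fell, and without any other single library 0 fell; 3 fell scaled by totals and 7 in limma after quantile normalization. zma-MIR398b (chromosome 7, 39887938 to 39888045) went from 16.2 ± 3.91 CPM in CW to 1.24 ± 1.01 in LW (mean ± SD, n = 3 each), 12.99-fold lower with an adjusted p of 0.0313, but another entry of that name at the same position (ENSRNA049997441) had other counts and was not called (adjusted p = 0.0707), so its level is uncertain; and zma-MIR528a (chromosome 1) from 2.96 ± 1.29 CPM to no count, at least 80.9-fold lower, but another entry of that name (ENSRNA049996714) had 0.172 against 1.68 CPM in CW replicate 3 and too few counts to be tested, so this level is uncertain too. Copper transporter 5 (Zm00001d020623) fell 14.02-fold from 94.3 ± 20.1 to 6.73 ± 2.14 CPM (adjusted p = 0.0192), and a pair of uclacyanin-3 genes, which encode blue copper proteins, rose 10.2-fold and 46.1-fold, while laccase-7 fell 8.69-fold. As a hypothesis, lower copper microRNAs may go with higher transcript of copper proteins: over 30 such genes the median log2 fold change lay 0.745 above that of all genes, but 2 rose, 1 fell and camera gave adjusted p = 0.0542 (adjusted p = 0.212 with an estimated correlation). Without CW replicate 3, 5 rose and 1 fell, without CW replicate 1 none was called, and scaled by totals 3 rose and 1 fell. Plastocyanins, also blue copper proteins, were not in that list, and the 2 called fell: plastocyanin homolog1 (Zm00001d035859) 2.81-fold from 3260 ± 511 to 1161 ± 104 CPM (adjusted p = 0.0442) and Zm00001d045620 20.9-fold (0.0269). Copper proteins thus went both ways, and the relation stays open. Precursor levels in these libraries, whose poly(A) selection the labels leave unsettled, are not levels of mature microRNA.

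Other classes of detoxification genes were examined beside the glutathione S-transferases. Of 132 cytochrome P450 genes 12 rose and 3 fell (camera adjusted p = 0.00731; 16 and 4 without CW replicate 3, 2 and 0 without CW replicate 1), with 18 and 1 scaled by totals, and of 99 UDP-glycosyltransferases 7 rose and 1 fell (adjusted p = 0.000116; 19 and 1 without CW replicate 3, 5 and 0 without CW replicate 1; 12 and 1 scaled by totals), led by UDP-glycosyltransferase 74B1 (Zm00001d008795), which rose 26.3-fold, and 84A1 (Zm00001d053715), which rose 16.75-fold. None of 13 class C ABC transporters and none of 25 MATE efflux genes passed edgeR's test over all genes, with camera adjusted p of 0.0542 and 0.0692; 5 of each were higher and 0 lower at an unadjusted p under 0.05, DESeq2 called 3 and 4 higher and limma 5 and 4, and edgeR called 2 and 4 higher without CW replicate 3 0 and 2 without CW replicate 1, and 2 and 3 scaled by totals. A joint rise of detoxification genes may therefore cover 2 of the 4 other classes tested, and neither passed with an estimated correlation (adjusted p = 0.212). Adjusted over the 8 lists first chosen, before the 2 copper lists were added, 3 of the 4 passed, the class C transporters at an adjusted p of 0.0452, so that class lies at the threshold. Of 21 chitinases 3 rose, Zm00001d048903, Zm00001d018966 and endochitinase precursor4 (camera adjusted p = 0.000829; adjusted p = 0.212 with an estimated correlation), and 9 rose without CW replicate 3 and 1 without CW replicate 1. Without CW replicate 2 or any 1 LW library no member of the lists of these opening paragraphs was called, except 1 glycosyltransferase that rose and 1 cytochrome P450 that fell without LW replicate 1. Of 26 pectinesterase-type genes 2 rose and 1 fell, of 49 U-box ubiquitin ligases 2 rose and of 60 class III peroxidases 3 rose and 1 fell (camera adjusted p = 0.0554 for each). Without CW replicate 3 these counts were 5 and 1, 8 and 1, and 6 and 5, and without CW replicate 1 they were 0 and 1, 0 and 0, and 0 and 0. They thus change with the libraries used. Scaled by totals they were 4 and 1, 4 and 0, and 3 and 0. Of 23 copper transport genes copper transporter 5 alone was called, while camera gave the list adjusted p = 0.241, and without CW replicate 3, 1 rose and 3 fell.

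CW replicate 3 lay apart from the other CW libraries. A swap between the groups needs an LW library out of place, and the lowest correlation within LW exceeded the highest between groups by 0.035. This argues against a swap. If CW replicates 1 and 2 stand for its unmixed profile, LW RNA mixed into this library would give the same LW fraction from every list. Summed organelle-encoded genes gave 0.893 (95% bootstrap interval over genes 0.862 to 0.933) and summed cytosolic ribosomal genes -0.00204 (-0.0801 to 0.0601), a difference of 0.895. Photosystem genes gave 0.171 (0.0484 to 0.273) and glutathione S-transferases 0.0507 (-0.395 to 0.449), and the intervals of these 2 lists and of the ribosomal genes overlap. Jasmonate and lignin genes went against mixing. The median of CW replicate 3 against CW replicates 1 and 2 was -0.43 on the log2 scale for jasmonate genes, where LW lay at 1.43, and -0.34 for lignin genes, where LW lay at 1.03. Other lists moved toward LW: chlorophyll synthesis at -0.55 (LW -0.90), carbon fixation at -0.29 (LW -0.36), photosystems at -0.51 (LW -2.51) and heat shock proteins at 0.13 (LW 0.79). On the component where CW replicate 3 scored -81.8, LW libraries scored -6.2, -5.0 and 31.9. A mixture would lie between the groups gene by gene, but the share of genes in which CW replicate 3 lay outside the other 5 libraries, 32.3%, fell between those of CW replicate 1 (30.6%) and CW replicate 2 (41.4%) and decides nothing. The values from lists speak against 1 share of LW RNA as the whole cause, but all take CW replicates 1 and 2 for the unmixed profile, so mixed RNA stays open. A first version, per gene among genes called without this library (0.201 for higher, 0.602 for lower genes), was replaced after its values were seen because that choice of genes biases it. An LW library wrongly labelled as CW replicate 3 is argued against by most values. Photosystem genes took 11.14% of its counts, against 11.53% and 13.29% in CW replicates 1 and 2 and 2.35% to 3.13% in LW. It correlated at 0.912 and 0.910 with those CW libraries and at most at 0.898 with LW, although its organelle-encoded genes lay near LW. The design names no group within CW, so no biological explanation was tested. Another wrong label or a difference in sampling or handling also stays open.

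The fall of photosystem genes and the rise of ribosomal genes were weighed together. A scaling effect of few genes that take many counts is argued against. The photosystem median stayed at -1.71 or lower over 5 scalings, of which quantile normalization, in limma on log2(FPKM + 1), gave that value. In the other 4 scalings 1 factor per library moves all genes alike. They therefore decide nothing about the gap between a list and all genes, and such a factor cannot cause one. The photosystem gap was -2.501 (95% bootstrap interval over genes -2.716 to -2.151). It ran from -2.849 to -1.92 over the 9 pairs of an LW and a CW library, and was -1.642 after quantile normalization. The ribosomal median lay 0.788 above that of all genes (95% bootstrap interval over genes 0.709 to 0.872). That gap ran from 0.543 to 1.102 over the 9 pairs of an LW and a CW library, and was 0.986 after quantile normalization. Younger leaf tissue in LW would raise cell division and histone genes, whose median lay at -0.223 relative to all genes; camera with an estimated correlation did not pass (adjusted p = 0.308), a condition added after the value was seen, so this cannot be told apart from the water regime. Collection at another time of day is also open, since the mean absolute log2 fold change of 26 clock genes, 1.16, lay at percentile 50.4 of 10000 random lists matched on expression. Drought and irrigation method, which the labels name, remain candidate explanations that these libraries cannot separate.

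More genes were detected in LW than in CW, 27310 ± 1145 against 23930 ± 1038 (n = 3 each), and with each library thinned to the 42927751 counts of the smallest 27130 ± 1074 against 23880 ± 992. The counts were treated as estimates from coverage rather than as reads. Thinning them therefore cannot show what equal read depth would give, and a part of depth in this difference stays open.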
